A study of Homo sapiens with 12 samples.

How the data were processed

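Polyadenylated RNA was sequenced from HepG2, a human cell line derived from a liver tumour, with 4 groups of 3 libraries each: wild-type cells and ARID1B-knockout cells (ARID1B-KO, made with CRISPR/Cas9), each given sorafenib at 5 µM or the same volume of DMSO for 48 h. Per the labels' protocols, libraries were prepared from 750 ng of total RNA with the KAPA mRNA HyperPrep kit and 9 PCR cycles, and sequenced as paired-end reads of 75 bp. The design text states that the 3 replicates of a condition are biological, and the labels do not say how many knockout clones they came from. Every library was assigned to its group by its title.

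Per the file headers, the authors deposited 1 Salmon transcript table per library, holding an estimated count for each transcript, its length, its effective length and its TPM. The estimated counts deposited by the authors are fractional and not normalized: 10.2% of the values above 0 were whole numbers to within 1e-06. The TPM values deposited by the authors, scaled to a fixed total within each library, were not used here, because the count model needs counts. Per the submitters' processing notes, the tools were Salmon, with no version given there, and DESeq2 1.46.0. The build was GRCh38, and the design text names Ensembl release 109. The highest transcript number in the files was 671676, whereas 21502 protein-coding transcripts of GENCODE release 44 (Ensembl 110) carry higher numbers, so the stated release is uncertain. Whether the quantification used strand, GC or sequence bias corrections is not given in the sources used here.

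Each table held 177456 transcripts. Transcripts were matched by unversioned identifier to GENCODE release 44, on GRCh38, from which gene names and coordinates were taken. The match covered 165533 transcripts (93.3%). The other 11923 held 2.87% to 3.20% of the counts of a library and were left out of the gene counts. They were tested separately. Estimated counts were summed to 35810 genes and rounded to whole numbers. Libraries held 19739582 to 29398257 estimated counts. Reads that fit near-identical sequences (paralogs, pseudogenes, alternate copies of a region) are divided by Salmon between them, so levels of such genes are uncertain.

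The main test was the quasi-likelihood F test of edgeR 4.0.16 with robust estimation and TMM normalization, in R 4.3.3. All 12 libraries entered a single fit with 4 group means, so the groups shared an estimate of the spread. Genes were kept by filterByExpr on the 4 groups, which left 12821 genes, and the common biological coefficient of variation was 0.152. The 5 contrasts were sorafenib against DMSO in each genotype, ARID1B-KO against wild type under each treatment, and the genotype by treatment interaction, which is the response in ARID1B-KO minus the response in wild type. P-values were adjusted by Benjamini-Hochberg over the genes tested in a contrast, and a gene was called at an adjusted p under 0.05. Every adjusted p of a gene is from this edgeR test. Fold changes are on the log2 scale with a standard error (SE) equal to the absolute log2 fold change divided by the square root of F. CPM are counts divided by the TMM library size, in the usual unit of edgeR. Group means are over n = 3 libraries, and most are printed without their SD. Where a group held 0 counts of a gene, the fold is a lower bound against a floor of 3 counts over the group. With 1 to 3 counts, the ratio is given with its exact 95% interval. Such bounds and intervals cover counting error only, because PCR copies were not separated from independent molecules.

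Gene lists were tested with camera of limma 3.58.1 at its preset correlation of 0.01 on log2 CPM with a prior count of 2. Of 41 lists, 38 had at least 5 members past the filter. P-values were adjusted over 38 lists and 5 contrasts (190 tests). In the results, each list called by camera is given with the numbers of members called over all genes and adjusted over the list alone, and with the adjusted p of camera with an estimated correlation. None of the camera calls held with an estimated correlation. The lists, the tests of the 5 contrasts and of the lists, and the rule for naming genes were fixed before the data were examined. Tests chosen afterwards are named as such where they are reported.

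Genes were named by this rule. ARID1B was named throughout. In each contrast the rule took the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups (for the interaction, without the overlap condition). It added the 4 members with the smallest adjusted p of each list called by camera, and the fixed genes DUSP6, SPRY4, ETV4, ETV5, CCND1, ASNS, DDIT3, TRIB3, ARID1A and ARID2. Part of the genes that the rule took are printed. Genes on the Y chromosome, XIST and clone identifiers were excluded.

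The procedure was tested on simulated counts over 12821 genes, with the wild-type DMSO gene means in every group and the real library sizes. In wild-type sorafenib 67 genes were changed 1.5-fold, 67 were changed 2-fold and 66 were changed 4-fold, and the other cholesterol synthesis genes were raised 1.5-fold. In ARID1B-KO DMSO the other genes of chromosome 17 were given a log2 change of -0.234. For sorafenib against DMSO in wild type the procedure recovered 47.8% of genes changed 1.5-fold, 62.7% of those changed 2-fold and 72.7% of those changed 4-fold. Far fewer genes were changed there than the 4543 called in the real contrast, so recovery in the real data may differ. For the interaction the procedure recovered 7.5%, 40.3% and 65.2%. Of the simulated calls for sorafenib in wild type, 3.5% of 142 were false, where the threshold allows 5% on average. For the interaction 6.9% of 87 were counted as false. That count included any called gene among those lowered on chromosome 17, whose interaction was real, so 6.9% cannot be set against 5%. The simulated contrast of sorafenib against DMSO in ARID1B-KO, where only the chromosome 17 genes differed, gave 0 calls. It thus held 0 false calls among the other genes and missed the small planted shift gene by gene.

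The alternatives were DESeq2 size factors, no filter on low counts, the DESeq2 1.42.0 Wald test, an offset for average transcript length, the replicate number as a block, fits of only the groups compared, leaving out each library, and camera with an estimated correlation or fry for the lists. Leaving out genes that switch on and off between replicates, and leaving out genome windows shifted between genotypes, were added after the data were seen.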

Results

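Polyadenylated RNA was measured in HepG2 cells, a line from a human liver tumour that keeps many hepatocyte functions, in 12 libraries. Wild-type cells and cells in which ARID1B had been targeted with CRISPR/Cas9 (ARID1B-KO) were each treated with DMSO or with 5 µM sorafenib for 48 h, with 3 biological replicates in each of the 4 groups. ARID1B is a DNA-binding subunit of the BAF chromatin remodelling complex, and sorafenib is an inhibitor of RAF and of growth factor receptor kinases used against liver cancer. The estimated counts per library were 29398257, 21823650 and 26798068 with DMSO and 29265843, 22470439 and 24398988 with sorafenib in wild type, and 22144626, 22153573 and 19739582 with DMSO and 27445013, 23302240 and 20135596 with sorafenib in ARID1B-KO, in the order of the replicate numbers. In total 12821 genes were tested. The first principal component, with 35.5% of the variance, ordered the libraries by genotype and, within a genotype, by treatment, and the second, with 27.4%, separated sorafenib from DMSO within each genotype. Mitochondrially encoded RNA made up 6.75% to 12.27% of the counts of a library. Values are means in CPM over n = 3 libraries, with SD only where a ± follows, or log2 fold changes ± SE. Adjusted p are from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment.

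The targeted gene was examined first. ARID1B (ENSG00000049618.25, GRCh38 chromosome 6, 156776020 to 157210779, plus strand) stood at 58.4, 61.9 and 66.7 CPM in the wild-type DMSO libraries and at 67.5, 69.1 and 62.3 CPM in the wild-type sorafenib libraries. In ARID1B-KO it stood at 26.39, 27.99 and 27.55 CPM with DMSO and at 35.6, 25.9 and 26.5 CPM with sorafenib. The log2 fold change of ARID1B-KO against wild type was -1.19 ± 0.11 in DMSO (edgeR adjusted p = 7.44e-06) and -1.18 ± 0.11 in sorafenib (adjusted p = 8.89e-06), and every ARID1B-KO library lay below every wild-type library. ARID1B transcript therefore remained in the knockout libraries at a reduced level. Sorafenib gave ARID1B a log2 fold change of 0.09 ± 0.11 in wild type (edgeR adjusted p = 0.566) and 0.10 ± 0.11 in ARID1B-KO (adjusted p = 0.484). The related subunits ARID1A, at 0.13 ± 0.11 (adjusted p = 0.387), and ARID2, at 0.14 ± 0.10 (adjusted p = 0.285), did not pass the test between genotypes in DMSO.

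**Figure D1:**
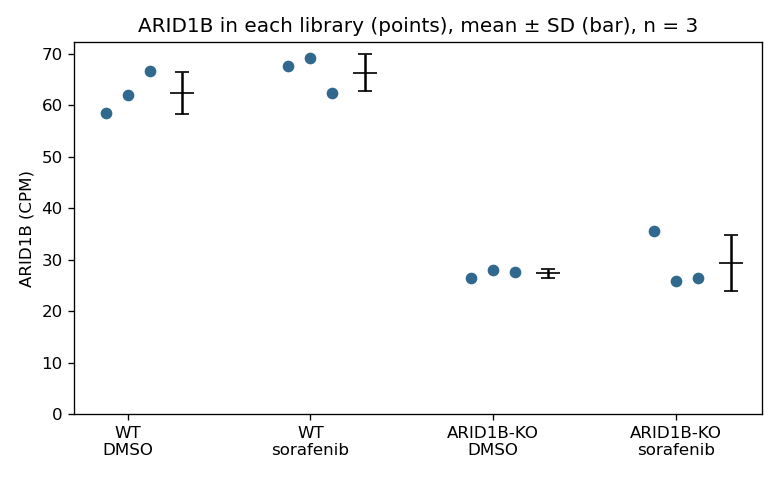
ARID1B in CPM (vertical axis) for each of the 12 libraries, shown as points by group (horizontal axis), with the group mean and SD as a bar beside them (n = 3). The ARID1B-KO libraries lie between 25.9 and 35.6 CPM and the wild-type libraries between 58.4 and 69.1 CPM.

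The response of wild-type cells to sorafenib gives the reference for the question in the study's title, whether ARID1B loss alters the response to the drug. SPRY4, an inhibitor of receptor tyrosine kinase signalling (chromosome 5, 142310427 to 142326455), fell in wild type from 54.1 to 4.77 CPM, with a log2 fold change of -3.50 ± 0.16 (edgeR adjusted p = 1.35e-08). The ETS transcription factor ETV4 (chromosome 17, 43527844 to 43579620) changed by -3.31 ± 0.10 (adjusted p = 5.15e-10), its relative ETV5 by -2.83 ± 0.09, and the ERK phosphatase DUSP6 by -2.98 ± 0.15. CYP7A1, the rate-limiting enzyme of bile acid synthesis (chromosome 8, 58490178 to 58500163), rose from 1.22 to 19.7 CPM, a log2 fold change of 4.01 ± 0.20 (edgeR adjusted p = 1.91e-08). BMF, a pro-apoptotic member of the BCL2 family, rose 7.83-fold (2.97 ± 0.10 on the log2 scale, adjusted p = 7.32e-10).

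Other large rises in wild type were the glutathione transferase GSTA2 (3.31 ± 0.13), the organic anion transporter SLC22A7 (3.06 ± 0.19), the kininogen gene KNG1 (2.81 ± 0.16), JAKMIP2 (2.81 ± 0.19) and MAB21L4 (2.79 ± 0.13). Other large falls were PPP2R2C, a regulatory subunit of protein phosphatase 2A (-4.07 ± 0.24), the homeobox gene HOXD1 (-3.96 ± 0.15), the chemokine CCL20 (-3.84 ± 0.17), the Notch target HEY1 (-3.50 ± 0.22), the hyaluronan-degrading gene CEMIP (-3.32 ± 0.22) and the xenobiotic-metabolising CYP1A1 (-3.15 ± 0.65, edgeR adjusted p = 0.00293). PLEKHM1 was at 0 counts in the wild-type DMSO libraries and at 782 counts over the sorafenib libraries, at least 277-fold higher. A transcript of near-equal length left out of the gene counts, chosen after its values were seen, held 270, 256 and 327 counts in the same DMSO libraries and 124, 0 and 0 in the sorafenib libraries, where PLEKHM1 held 228, 285 and 269. The assignment of PLEKHM1 reads was therefore uncertain. CCND1, which encodes cyclin D1, was at -0.06 ± 0.09 (adjusted p = 0.648).

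In the list of RAS-ERK output genes, 11 of 23 members fell and 1 rose in wild type, and 14 fell and 1 rose when adjusted over the list alone (camera adjusted p = 1.92e-06; adjusted p = 0.199 with an estimated correlation). Among DNA replication genes, 28 of 40 fell and 2 rose, with the same counts adjusted over the list alone (camera adjusted p = 1.25e-07; adjusted p = 0.473 with an estimated correlation). They included RRM2, a subunit of ribonucleotide reductase, at -1.16 ± 0.11 and the cell cycle regulator E2F1 at -0.94 ± 0.09. Of 32 mitosis genes, 11 fell and 1 rose, and 13 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.00461; adjusted p = 0.818 with an estimated correlation). The mitotic kinase PLK1 was at -0.39 ± 0.09.

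Of 36 complement and coagulation factors, 27 rose in wild type and 1 fell, and 28 rose and 1 fell adjusted over the list alone (camera adjusted p = 8.99e-08; adjusted p = 0.666 with an estimated correlation). The fibrinogen chains FGA (1.66 ± 0.16) and FGG (1.64 ± 0.17) were among them. Of 29 hepatocyte secreted proteins, 16 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 8.73e-05; adjusted p = 0.77 with an estimated correlation). The apolipoprotein APOC3 (2.45 ± 0.10) and haptoglobin, HP (2.11 ± 0.19), were among those that rose. Albumin RNA made up 3.26% to 3.42% of the counts in wild-type DMSO libraries and 4.14% to 4.38% in wild-type sorafenib libraries. Hepatocyte transcription factors had 12 of 22 members higher and 4 lower, and 13 and 4 adjusted over the list alone (camera adjusted p = 0.00978; adjusted p = 0.177 with an estimated correlation). CEBPA rose (0.91 ± 0.07), whereas NR0B2, a repressor of bile acid synthesis, fell (-2.19 ± 0.09).

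All called members of the cholesterol synthesis list rose in wild type, 21 of 25, and 22 adjusted over the list alone (camera adjusted p = 1.25e-07; adjusted p = 0.107 with an estimated correlation), among them HMGCS1 (1.01 ± 0.10). Of 24 PPARA target and fatty acid oxidation genes, 16 rose and 1 fell, and 17 and 1 adjusted over the list alone (camera adjusted p = 4.69e-06; adjusted p = 0.228 with an estimated correlation), among them CREB3L3 (1.71 ± 0.12). Of 20 fatty acid synthesis genes, 10 rose and 1 fell, and 11 and 1 adjusted over the list alone (camera adjusted p = 0.000893; adjusted p = 0.595 with an estimated correlation). The acetyl-CoA synthetase ACSS2 rose by 1.78 ± 0.08 on the log2 scale.

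Of 28 p53 targets, 17 rose in wild type and 4 fell, and 19 and 4 adjusted over the list alone (camera adjusted p = 0.000198; adjusted p = 0.0867 with an estimated correlation), including the antiproliferative gene BTG2 at 1.13 ± 0.12. Of 39 ATF4 and amino acid response genes, 18 fell and 8 rose, and 19 and 9 adjusted over the list alone (camera adjusted p = 0.000746; adjusted p = 0.199 with an estimated correlation). Asparagine synthetase, ASNS, fell (-2.07 ± 0.11), while DDIT3 at 0.42 ± 0.20 (edgeR adjusted p = 0.121) and TRIB3 at -0.17 ± 0.08 (adjusted p = 0.105) did not pass the test. Heat shock genes had 8 of 19 members lower and 0 higher, and 9 and 0 adjusted over the list alone (camera adjusted p = 0.0021; adjusted p = 0.332 with an estimated correlation). Endoplasmic reticulum chaperones had 11 of 29 lower and 0 higher under both adjustments (camera adjusted p = 0.0101; adjusted p = 0.818 with an estimated correlation). Replication-dependent histones, whose mRNAs mostly lack poly(A) tails, had 8 of 17 higher and 0 lower, and 10 and 0 adjusted over the list alone (camera adjusted p = 0.000317; adjusted p = 0.0867 with an estimated correlation). Over all genes, 4543 were called in wild type by edgeR, 2239 higher and 2304 lower, of which 475 and 356 changed over 2-fold. The groups did not overlap for 50.8% of genes, where chance gives 10%. With an offset for transcript length 2867 were called.

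In ARID1B-KO with sorafenib, SPRY4 fell from 38.6 to 1.54 CPM (-4.66 ± 0.19, edgeR adjusted p = 3.88e-09), ETV4 changed by -4.30 ± 0.11, ETV5 by -3.57 ± 0.09 and DUSP6 by -3.32 ± 0.16. BMF rose 12.9-fold (3.69 ± 0.10, adjusted p = 8.12e-11), and the secreted phospholipase PLA2G1B rose from 0.405 to 6.07 CPM (3.89 ± 0.31). CCL20 (-4.92 ± 0.21), HOXD1 (-4.56 ± 0.15), the monocarboxylate transporter family member SLC16A6 (-4.22 ± 0.60) and the glycolytic enzyme HK2 (-3.61 ± 0.17) fell. PLEK2 (3.47 ± 0.23), SFXN3 (3.34 ± 0.65), CYP3A43 (3.27 ± 0.39), CLIC3 (3.23 ± 0.40) and the betaine transporter SLC6A12 (3.14 ± 0.23) rose. SFXN3 (edgeR adjusted p = 0.00263) varied widely among replicates, at 29.3 ± 24.1 CPM with sorafenib and 2.90 ± 1.4 CPM with DMSO. PLEKHM1 was at least 204-fold higher. The transcript left out of the gene counts held 0, 148 and 184 counts in the ARID1B-KO DMSO libraries, where PLEKHM1 was at 0, and 0 in the sorafenib libraries. WDR46 was at -5.62 ± 1.80 (edgeR adjusted p = 0.0319), but it was itself a gene that switched on and off among replicates, at 0, 7.515 and 0 CPM in the wild-type sorafenib libraries.

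Of 40 DNA replication genes, 33 fell and 0 rose in ARID1B-KO, and 35 and 0 adjusted over the list alone (camera adjusted p = 2.13e-11; adjusted p = 0.311 with an estimated correlation). UHRF1, which maintains DNA methylation, was at -1.44 ± 0.09 and the licensing factor CDC6 at -1.34 ± 0.10. Of 32 mitosis genes, 16 fell and 2 rose under both adjustments (camera adjusted p = 0.0121; adjusted p = 0.818 with an estimated correlation). RAS-ERK output genes had 11 of 23 lower and 2 higher under both adjustments (camera adjusted p = 0.000241; adjusted p = 0.297 with an estimated correlation). Heat shock genes had 15 of 19 lower and 0 higher, and 17 lower and 1 higher adjusted over the list alone (camera adjusted p = 3.07e-05; adjusted p = 0.199 with an estimated correlation), with the co-chaperone FKBP4 at -1.42 ± 0.09. ATF4 and amino acid response genes had 22 of 39 lower and 9 higher, and 23 and 10 adjusted over the list alone (camera adjusted p = 0.00149; adjusted p = 0.214 with an estimated correlation). ASNS was at -2.18 ± 0.12 and TRIB3 at -0.51 ± 0.08.

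In ARID1B-KO with sorafenib, complement and coagulation factors had 28 of 36 higher and 1 lower under both adjustments (camera adjusted p = 1.11e-07; adjusted p = 0.667 with an estimated correlation), with KNG1 at 2.81 ± 0.15. Hepatocyte secreted proteins had 20 of 29 higher and 2 lower under both adjustments (camera adjusted p = 1.74e-05; adjusted p = 0.714 with an estimated correlation), with APOC3 at 2.68 ± 0.10. Albumin RNA was 5.08% to 5.59% of the counts in ARID1B-KO DMSO libraries and 6.86% to 9.63% in ARID1B-KO sorafenib libraries. Hepatocyte transcription factors had 7 of 22 higher and 4 lower under both adjustments, and camera did not call the list (adjusted p = 0.346; adjusted p = 0.674 with an estimated correlation). PPARA targets had 18 of 24 higher and 0 lower under both adjustments (camera adjusted p = 6.27e-06; adjusted p = 0.231 with an estimated correlation), with ANGPTL4 at 2.56 ± 0.26. Cholesterol synthesis genes had 16 of 25 higher and 0 lower, and 17 and 0 adjusted over the list alone (camera adjusted p = 0.000703; adjusted p = 0.267 with an estimated correlation). Histones had 9 of 17 higher and 0 lower under both adjustments (camera adjusted p = 0.000334; adjusted p = 0.0867 with an estimated correlation). p53 targets had 18 of 28 higher and 4 lower under both adjustments (camera adjusted p = 0.00158; adjusted p = 0.107 with an estimated correlation), with TP53INP1 at 1.22 ± 0.09. ABC transporters and efflux genes had 9 of 19 higher and 2 lower under both adjustments (camera adjusted p = 0.0417; adjusted p = 0.818 with an estimated correlation), with the vault protein gene MVP at 2.13 ± 0.13 and the efflux pump ABCG2 at -1.19 ± 0.15. Over all genes edgeR called 5982, 2947 higher and 3035 lower, of which 866 and 535 changed over 2-fold. The groups did not overlap for 52.9% of genes, where chance gives 10%.

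The responses of the genotypes were compared across genes. Of genes called in both, 1751 rose in both, 1866 fell in both and 20 went in opposite directions, where independent lists would share 515 and 545. Across the 12821 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.607 and a Spearman correlation of 0.751, and the Pearson correlation was 0.87 over the genes called in wild type. With no filter on low counts the Pearson correlation over all genes was 0.215. The total least squares slope of ARID1B-KO on wild type was 1.293. Among the 6888 genes called in either genotype, 93.1% had the same sign in both.

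**Figure D2:**
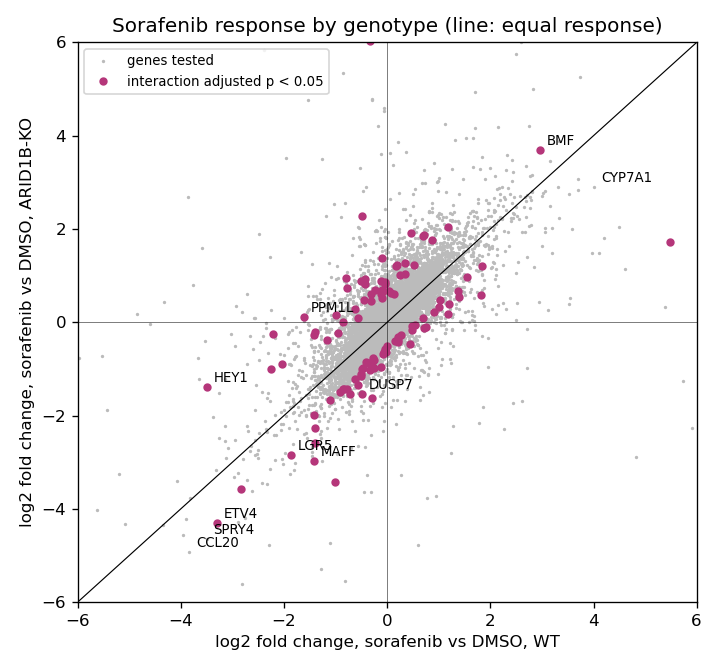
Log2 fold change of sorafenib against DMSO in wild type (horizontal axis) and in ARID1B-KO (vertical axis) for each gene tested (grey points), with genes past the interaction test in colour and the line of equal response. The axes end at 6 in either direction and leave out 41 genes, and ETV4, at -3.31 and -4.30, lies below the line.

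The genotypes were next compared without the drug. CDH2, which encodes N-cadherin (chromosome 18, 27932879 to 28177946), fell from 70.2 CPM in wild type to 0.344 CPM in ARID1B-KO, a log2 fold change of -7.65 ± 0.38 (edgeR adjusted p = 5.58e-08). GPC3, a cell surface proteoglycan that marks liver tumours (chromosome X, 133535745 to 133987100), stood at 481 CPM in wild type and 14.7 CPM in ARID1B-KO (-5.03 ± 0.22, adjusted p = 1.39e-08). The phospholipid flippase gene ATP10A was at 0 counts in ARID1B-KO, at least 182-fold lower, and RTL8C was lower by a ratio of 306 (95% interval 104 to 1480). In the other direction, the glycerol and water channel AQP9 was at 0 counts in wild type and 1853 counts over the ARID1B-KO libraries, at least 745-fold higher, and the transcription factor TWIST2 was at least 138-fold higher. MEGF6 (6.11 ± 0.27), COL26A1 (5.68 ± 0.26), MYRIP (5.49 ± 0.36), the ferric reductase CYBRD1 (4.63 ± 0.40), ALDH8A1 (4.42 ± 0.30) and the adhesion gene NRCAM (4.22 ± 0.19) were higher, and KLF12 (-6.30 ± 0.49), XIRP2 (-5.19 ± 0.32), MEP1A (-5.12 ± 0.31) and CAP2 (-5.08 ± 0.80) were lower.

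In DMSO, NF-kB and acute phase genes had 14 of 21 members lower in ARID1B-KO and 2 higher, and 15 and 2 adjusted over the list alone (camera adjusted p = 4.04e-05; adjusted p = 0.119 with an estimated correlation). The fibrinogen chain FGB was at -3.95 ± 0.21 and the NF-kB inhibitor TNFAIP3 at -1.02 ± 0.08. WNT targets had 12 of 21 lower and 3 higher under both adjustments (camera adjusted p = 0.00168; adjusted p = 0.413 with an estimated correlation). The WNT antagonist DKK1 was at -2.78 ± 0.13, and APCDD1, at 0 counts in ARID1B-KO, was at least 89.9-fold lower. YAP and TEAD targets had 8 of 19 lower and 0 higher under both adjustments (camera adjusted p = 0.00357; adjusted p = 0.572 with an estimated correlation), with CCN1 at -4.08 ± 0.26 and ANKRD1 at -2.98 ± 0.26. RAS-ERK output genes had 12 of 23 lower and 2 higher, and 14 and 3 adjusted over the list alone (camera adjusted p = 0.00259; adjusted p = 0.401 with an estimated correlation). DUSP6 was at -0.83 ± 0.14, SPRY4 at -0.48 ± 0.14 and ETV4 at -0.53 ± 0.09, ETV5 did not pass the test at -0.13 ± 0.08 (edgeR adjusted p = 0.228), and CCND1 was higher at 0.58 ± 0.09.

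In DMSO, cholesterol synthesis genes had 15 of 25 higher and 0 lower in ARID1B-KO, and 17 and 0 adjusted over the list alone (camera adjusted p = 1.74e-05; adjusted p = 0.177 with an estimated correlation), with mevalonate kinase, MVK, at 1.03 ± 0.11. p53 targets had 15 of 28 higher and 1 lower, and 16 and 1 adjusted over the list alone (camera adjusted p = 8.73e-05; adjusted p = 0.0867 with an estimated correlation), with BTG2 at 1.56 ± 0.12. NRF2 targets had 10 of 29 higher and 2 lower under both adjustments (camera adjusted p = 0.0121; adjusted p = 0.401 with an estimated correlation). The aldo-keto reductases moved apart, AKR1B10 at 2.34 ± 0.12 and AKR1C2 at -2.33 ± 0.10. Heat shock genes had 8 of 19 higher and 0 lower, and 10 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0143; adjusted p = 0.476 with an estimated correlation). Endoplasmic reticulum chaperones had 10 of 29 lower and 0 higher, and 15 and 0 adjusted over the list alone (camera adjusted p = 0.000551; adjusted p = 0.817 with an estimated correlation). Complement and coagulation factors had 13 of 36 lower and 5 higher, and 14 and 5 adjusted over the list alone (camera adjusted p = 0.0143; adjusted p = 0.875 with an estimated correlation), although albumin took a larger share of the counts than in wild type.

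Extracellular matrix genes in ARID1B-KO with DMSO had 5 of 18 lower and 2 higher, and 6 and 2 adjusted over the list alone (camera adjusted p = 0.0131; adjusted p = 0.818 with an estimated correlation), with the protease inhibitor TIMP1 at -2.82 ± 0.22. Histones had 4 of 17 lower and 0 higher under both adjustments (camera adjusted p = 0.0204; adjusted p = 0.199 with an estimated correlation). Metallothioneins had 3 of 6 lower and 0 higher, and 4 and 0 adjusted over the list alone (camera adjusted p = 0.0296; adjusted p = 0.582 with an estimated correlation). Cytosolic ribosomal proteins had 5 of 50 lower and 0 higher, and 2 and 0 adjusted over the list alone (camera adjusted p = 0.0129; adjusted p = 0.906 with an estimated correlation). These genes have many processed pseudogenes, so their counts are uncertain. Without the genome windows that shifted between genotypes, camera no longer called WNT targets (adjusted p = 0.0516) or extracellular matrix genes (adjusted p = 0.0516) in DMSO, and too few histones were left to test. Over all genes edgeR called 3563 in DMSO, 1829 higher and 1734 lower in ARID1B-KO, of which 369 and 545 differed over 2-fold. The groups did not overlap for 42.2% of genes, where chance gives 10%. The mean effective transcript length was 931.9 to 981.6 in ARID1B-KO DMSO libraries and 828.1 to 910.0 in wild-type DMSO libraries, and with an offset for transcript length 2189 genes were called.

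Under sorafenib, the comparison of the genotypes asks how the treated cells differed. CDH2 was at -8.05 ± 0.40 (edgeR adjusted p = 5.86e-08), RTL8C at -7.17 ± 0.45, MEP1A at -6.61 ± 0.38, the sulfotransferase CHST9 at -6.07 ± 0.57 and the matrix glycoprotein EMILIN1 at -5.22 ± 0.25. ATP10A was at least 125-fold lower and APCDD1 at least 48.6-fold lower. MEGF6 (6.94 ± 0.27), COL26A1 (6.26 ± 0.28), CYBRD1 (5.96 ± 0.44), MYRIP (5.80 ± 0.37), the phosphatase PPM1L (5.78 ± 0.24) and NRCAM (5.28 ± 0.21) were higher, AQP9 by a ratio of 328 (95% interval 90.5 to 2720) and NEGR1 by a ratio of 551 (95% interval 98.4 to 21800). ZBTB12, at least 176-fold lower, was itself a gene that switched among replicates, at 8.653, 0 and 9.088 CPM in the ARID1B-KO DMSO libraries, and RPS27P4, at least 165-fold lower, is a pseudogene, so both rest on uncertain counts.

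DNA replication genes were lower in ARID1B-KO under sorafenib, 21 of 40 with 0 higher, and 23 lower and 2 higher adjusted over the list alone (camera adjusted p = 1.92e-06; adjusted p = 0.551 with an estimated correlation). Thymidine kinase, TK1, was at -1.01 ± 0.10. RAS-ERK output genes had 13 of 23 lower and 2 higher, and 14 and 2 adjusted over the list alone (camera adjusted p = 0.000143; adjusted p = 0.293 with an estimated correlation). SPRY4 was at -1.64 ± 0.20, ETV4 at -1.52 ± 0.10, DUSP6 at -1.17 ± 0.16 and ETV5 at -0.87 ± 0.09. YAP and TEAD targets had 12 of 19 lower and 0 higher under both adjustments (camera adjusted p = 5.68e-05; adjusted p = 0.342 with an estimated correlation), with CCN2 at -1.88 ± 0.16. NF-kB and acute phase genes had 13 of 21 lower and 2 higher under both adjustments (camera adjusted p = 8.73e-05; adjusted p = 0.136 with an estimated correlation). WNT targets had 12 of 21 lower and 4 higher, and 14 and 4 adjusted over the list alone (camera adjusted p = 0.00553; adjusted p = 0.509 with an estimated correlation), with DKK1 at -3.70 ± 0.13 and the receptor LGR5 at -2.26 ± 0.13.

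p53 targets had 13 of 28 higher and 0 lower in ARID1B-KO under sorafenib, and 15 and 0 adjusted over the list alone (camera adjusted p = 1.22e-05; adjusted p = 0.0867 with an estimated correlation), with SESN1 at 0.92 ± 0.10. Drug metabolism enzymes had 9 of 23 higher and 2 lower, and 9 and 3 adjusted over the list alone (camera adjusted p = 0.0183; adjusted p = 0.199 with an estimated correlation). The glutathione transferases GSTA1 (2.28 ± 0.14) and GSTA2 (2.15 ± 0.11), which are near-identical in sequence, were among them. Cholesterol synthesis genes had 9 of 25 higher and 0 lower, and 10 and 0 adjusted over the list alone (camera adjusted p = 0.0101; adjusted p = 0.389 with an estimated correlation). Endoplasmic reticulum chaperones had 11 of 29 lower and 0 higher, and 15 and 0 adjusted over the list alone (camera adjusted p = 0.000317; adjusted p = 0.816 with an estimated correlation). Cytosolic ribosomal proteins had 4 of 50 lower and 0 higher, and 0 called adjusted over the list alone (camera adjusted p = 0.00401; adjusted p = 0.876 with an estimated correlation). Over all genes edgeR called 3463, 1695 higher and 1768 lower, of which 434 and 417 differed over 2-fold. The groups did not overlap for 42.7% of genes, where chance gives 10%. The mean effective transcript length was 889.2 to 947.9 in ARID1B-KO sorafenib libraries and 845.1 to 858.4 in wild-type sorafenib libraries, and with an offset for transcript length 2046 genes were called. Without the shifted windows camera no longer called drug metabolism enzymes (adjusted p = 0.167) or WNT targets (adjusted p = 0.109). Of the genes called under both treatments, 1024 were higher in both, 962 lower in both and 31 opposite, where independent lists would share 242 and 239.

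**Figure D3:**
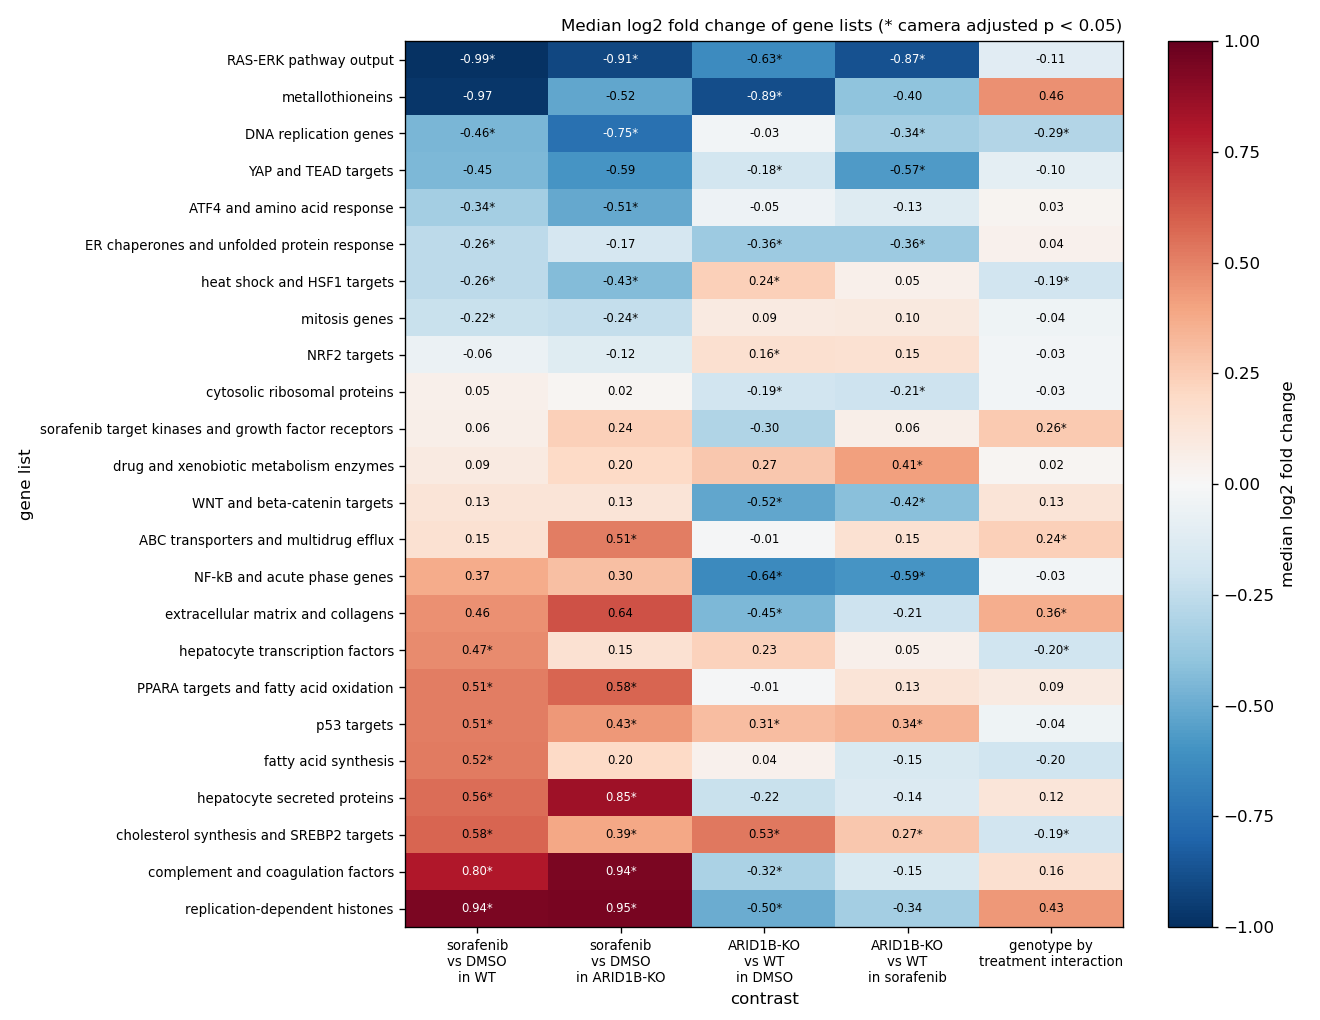
Median log2 fold change (colour and number) of each gene list called by camera in at least 1 contrast (vertical axis) in the 5 contrasts (horizontal axis) and the colour scale ending at 1 in either direction, with an asterisk where the camera adjusted p was under 0.05. Among RAS-ERK output genes the median was -0.99 for sorafenib in wild type and -0.91 in ARID1B-KO, no asterisk held with an estimated correlation, and 0 of the 10 medians with a member at 0 counts moved when that member was set at its bound.

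Neighbouring genes shifted together between the genotypes. Of 151 windows of 20 Mb with at least 20 tested genes, 13 had a median log2 fold change of ARID1B-KO against wild type in DMSO beyond 0.2, 6 lower and 7 higher. The 3 windows of chromosome 6 from 0 to 60 Mb each had a median of -0.25, and the 3 windows of chromosome 17 from 40 to 100 Mb lay between -0.24 and -0.23. The 6 windows of chromosome 2 from 140 to 260 Mb lay between 0.21 and 0.32, and the window of chromosome 21 from 40 to 60 Mb had a median of 0.42. All 13 had the same sign in the sorafenib libraries. Genes in these windows were called in DMSO in 40.4% of cases, against 26.5% elsewhere. The windows were chosen by the fold changes of this same contrast, which by itself favours a higher share of calls inside them.

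**Figure D4:**
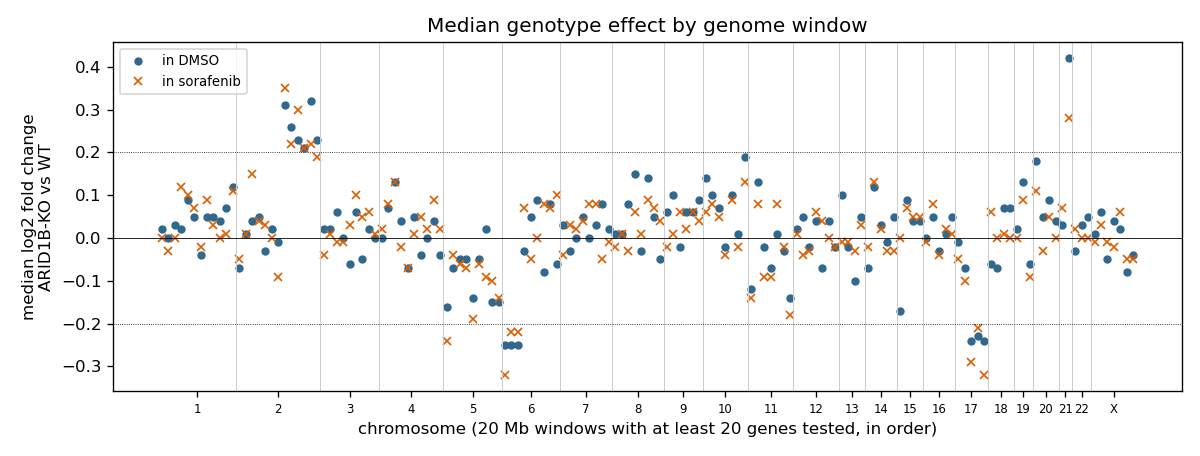
Median log2 fold change of ARID1B-KO against wild type (vertical axis) in 151 windows of 20 Mb in genome order (horizontal axis), in DMSO (circles) and in sorafenib (crosses), with dotted lines at 0.2 in either direction. The 13 windows beyond the lines in DMSO lie on chromosomes 2, 6, 17 and 21.

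Whether the response to sorafenib itself differed by genotype was tested by the interaction. ETV4 fell further in ARID1B-KO than in wild type, with an interaction of -0.99 ± 0.14 on the log2 scale (edgeR adjusted p = 0.0136), as did ETV5 (-0.74 ± 0.12, adjusted p = 0.0261). SPRY4 at -1.16 ± 0.25 (adjusted p = 0.0531) and DUSP6 at -0.34 ± 0.21 (adjusted p = 0.492) did not pass the test. Of 23 RAS-ERK output genes 3 were negative and 0 positive, and 5 and 0 adjusted over the list alone, with a median of -0.11, and camera did not call the list (adjusted p = 0.117; adjusted p = 0.816 with an estimated correlation). SSUH2 (chromosome 3, 8619386 to 8745040) had an interaction of -1.33 ± 0.13 (adjusted p = 0.00185), standing at 29.7 and 24.1 CPM in wild type with DMSO and sorafenib and at 24.8 and 7.97 CPM in ARID1B-KO. The small GTPase gene RAB17 (chromosome 2, 237574322 to 237601614) went from 37.7 to 27.99 CPM in wild type and from 56.4 to 99.2 CPM in ARID1B-KO, an interaction of 1.25 ± 0.14 (adjusted p = 0.0034).

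HEY1 had the largest positive interaction by the naming rule, 2.12 ± 0.32 (edgeR adjusted p = 0.0181), going from 10.0 to 0.879 CPM in wild type and from 1.89 to 0.717 CPM in ARID1B-KO. PPM1L (1.72 ± 0.32), the pseudogene SDHAP1 (1.52 ± 0.26), CCDC150 (1.47 ± 0.17), FAM13A (1.45 ± 0.30), ZNF117 (1.41 ± 0.16) and TGFBR3 (1.24 ± 0.25) were also positive. The transcription factor MAFF (-1.57 ± 0.31), MRAS (-1.25 ± 0.18), CPLX2 (-1.20 ± 0.21), the phosphatase DUSP7 (-1.04 ± 0.20), PTP4A3 (-1.02 ± 0.19) and LGR5 (-0.999 ± 0.17) were negative. In total edgeR called 107 genes, 48 positive and 59 negative. Of these, 50 responded more in ARID1B-KO, 20 responded less and 37 had fold changes of opposite sign.

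DNA replication genes had a negative interaction as a list (camera adjusted p = 2.11e-08; adjusted p = 0.404 with an estimated correlation). Over all genes 2 of 40 were called negative, UHRF1 at -0.60 ± 0.12 and MCM7 at -0.52 ± 0.11, and 14 adjusted over the list alone. Heat shock genes (1 of 19 negative, and 2 adjusted over the list alone; camera adjusted p = 0.000893; adjusted p = 0.297 with an estimated correlation) and cholesterol synthesis genes (1 of 25, and 2 adjusted over the list alone; camera adjusted p = 0.00956; adjusted p = 0.385 with an estimated correlation) also had a negative interaction as lists by camera. The called members were FKBP4 (-0.57 ± 0.12) and HMGCS1 (-0.69 ± 0.14). Hepatocyte transcription factors had a negative interaction as a list (camera adjusted p = 0.0121; adjusted p = 0.177 with an estimated correlation), with CEBPA at -0.68 ± 0.10 and NR1I2 at 0.90 ± 0.18 called, and 1 positive and 3 negative adjusted over the list alone. Extracellular matrix genes (camera adjusted p = 0.0169; adjusted p = 0.818 with an estimated correlation), sorafenib target kinases (camera adjusted p = 0.0169; adjusted p = 0.818 with an estimated correlation) and ABC transporters (camera adjusted p = 0.0454; adjusted p = 0.823 with an estimated correlation) had a positive interaction as lists by camera. They had 0 members called by edgeR over all genes, and 0, 0 and 2 adjusted over the list alone, and without the shifted windows extracellular matrix genes were not called (camera adjusted p = 0.174).

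The interaction count, 107, depended on nearly every library and on the method. Leaving out 1 library lowered the count in 11 of 12 cases. Such a fit also rests on fewer libraries and repeats the filter on low counts, so a lower count need not reflect that library alone. The count was 73 without wild-type DMSO replicate 1 and rose to 138 without ARID1B-KO sorafenib replicate 3. It was 5 without wild-type sorafenib replicate 2, 12 without ARID1B-KO sorafenib replicate 2, 13 without wild-type DMSO replicate 2, 16 without wild-type sorafenib replicate 3 and 17 without wild-type DMSO replicate 3, 21 without ARID1B-KO DMSO replicate 2 or replicate 3, 22 without wild-type sorafenib replicate 1 or ARID1B-KO sorafenib replicate 1, and 25 without ARID1B-KO DMSO replicate 1. It was 584 with the DESeq2 Wald test and 2, SSUH2 and RAB17, with an offset for transcript length.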

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

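The tests of copy number, of the shifted windows as the source of calls, of alternate copies, of counting error and of permuted residuals were chosen after the results were seen, and the others were planned.

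The test of the interaction itself, with edgeR, singled out 107 genes whose response to sorafenib differed between the genotypes. Among signalling genes the interaction was -0.99 for ETV4, -0.74 for ETV5, -0.57 for SPRED2, -1.04 for DUSP7, -1.02 for PTP4A3, -1.25 for MRAS, -0.65 for TNFAIP3, -0.91 for DKK1, -1 for LGR5, 2.12 for HEY1 and 1.24 for TGFBR3 on the log2 scale. Among transcription, replication and stress genes it was -0.68 for CEBPA, 0.9 for NR1I2, -1.57 for MAFF, -0.6 for UHRF1, -0.52 for MCM7, -0.57 for FKBP4, 0.7 for TP53INP1 and 0.72 for BMF. Among metabolic genes it was -0.69 for HMGCS1, -0.6 for GPAM, -0.71 for HMOX1 and 0.93 for CYP3A7. For the remaining named genes it was 1.72 for PPM1L, 1.52 for SDHAP1, 1.47 for CCDC150, 1.45 for FAM13A, 1.41 for ZNF117, 1.25 for RAB17, -1.33 for SSUH2 and -1.2 for CPLX2. The camera adjusted p of the interaction was 2.11e-08 for DNA replication genes, 0.000893 for heat shock genes, 0.00956 for cholesterol synthesis, 0.0121 for hepatocyte transcription factors, 0.0169 for extracellular matrix genes, 0.0169 for sorafenib target kinases and 0.0454 for ABC transporters. With an estimated correlation the adjusted p, in the same order, was 0.404, 0.297, 0.385, 0.177, 0.818, 0.818 and 0.823.

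Whether chance alone can give so many interaction calls stayed open. In 100 splits of the genotype labels within each treatment, 4 called as many genes as the real split, itself included, with 110 in the real split of that fit and 735 in the highest other. By the rule set before the data were examined, fewer than 5 of 100, chance would have been excluded. That rule was set aside after the result was seen, because the exact 95% interval of the share ran from 1.1% to 9.93%. That interval treats the splits as independent draws. They were drawn without repeats from a limited number of possible splits, so it does not strictly apply. The count of 4 also depends on which splits were drawn, so this test decided nothing. The 3 larger splits, with 735, 412 and 119 genes, kept the labels of a treatment and relabelled 4 libraries of the other, which carries the genotype effect into the contrast. Splits that call several times the real count point to a structure of the libraries, here at least the genotype effect that they carry in, and no test looked for another. In 100 permutations of the residuals with limma-trend, 4 gave as many calls as the real 101, itself included. The highest other gave 1974, and the median of the others was 0. The residuals were taken from a fit without the interaction, so they still held any real interaction, which a permutation could carry back into the contrast.

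For the other contrasts, 3 libraries against 3 make 10 splits, and 1 of 10, the real split, is the lowest share they can give. The real split of the 6 libraries called 4778 genes for sorafenib in wild type (highest other 1), 5207 in ARID1B-KO (highest other 1), 2978 for ARID1B-KO in DMSO (highest other 1) and 3190 in sorafenib (highest other 0). Every other split mixes the compared groups, so a real effect widens the spread within each side. Their low counts therefore do not measure how many calls arise by chance.

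Few of the transcripts left out of the gene counts were called. Of 2206 tested, edgeR called 27 for sorafenib in wild type, 37 for sorafenib in ARID1B-KO, 31 for ARID1B-KO in DMSO, 18 for ARID1B-KO in sorafenib and 4 for the interaction. Each is a smaller share than among the genes tested, of which 35.4%, 46.7%, 27.8%, 27% and 0.8% were called in the same order.

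Neighbouring genes on chromosomes 2, 6, 17 and 21 shifted together between the genotypes in 13 windows. Bias by GC content and length was argued against, since 11 of the 13 stayed beyond 0.2 after a smooth trend on both was removed, and chance placement of genes was argued against, since 0 of 100 shuffles gave as many windows (highest 2). In the sorafenib libraries 74.2% of the genes in these windows (interval 70.9% to 78%) lay on the side of their window, which any stable difference between the cells predicts, so a copy number difference was left open and not singled out. Of the 3563 genotype calls in DMSO, 471 lay in these windows, and 3044 genes were called without them. With 1166 tested genes the windows could not have held most calls, so the outcome of that test was fixed in advance. Regional shifts within 0.2 were not examined as a source of calls. Loss of ARID1B and the history of the knockout cells were not told apart by any test here, because all ARID1B-KO libraries share both.

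In 85 genes a library of a group was near 0 while another replicate was not. Counting error was argued against, since Poisson counting at the real depths was expected to give 1.1e-23 such genes among all 12821 tested. Their median level was 6.62 CPM against 23.3 CPM for all genes tested, which by the rule set beforehand spoke for low depth, but low depth acts through counting error, which was expected to give almost none of these genes, so that rule was wrong. Assignment of reads to another copy of the same sequence may be the source on chromosome 6 from 28 to 34 Mb, where the reference has alternate sequences and 17 of 95 genes (17.9%) switched, against 0.54% outside both regions examined, an odds ratio of 40.4 (95% interval 21.3 to 73.6, Fisher's exact test, p = 2.98e-20). On chromosome 17 from 45 to 47 Mb 0 of 18 genes switched (odds ratio 0, interval up to 43.3), which leaves it open there, and it was not tested for the 68 switching genes outside both regions.

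The response to sorafenib was larger in ARID1B-KO across genes, with a mean ratio of response sizes of 1.212 (1.244, 1.176 and 1.215 in 3 splits of independent libraries). Larger noise of single ARID1B-KO libraries was argued against, because noise that is independent between libraries cancels in this ratio. The switching genes were also argued against, since without them and the other genes of their regions the ratio was 1.203 (1.168 to 1.223). A stronger response in the knockout cells may be a property of the cells, as a hypothesis found and tested on the same data. A technical difference shared by all libraries of a group does not cancel in the ratio. Mean effective transcript length differed between groups, and the ratio was not computed with an offset for it. Among the 4543 genes called in wild type, 52.9% had the larger response in ARID1B-KO and the regression slope was 0.881, a choice of genes that favours wild type. The splits tested neither such shared differences nor the history of the knockout cells.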

How the results depend on the processing

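The fits without switching genes and without shifted windows were chosen after the data were seen, and the other alternatives were planned. The interaction, 107 genes, was the least stable result: the DESeq2 Wald test called 584, including all 107, the offset for average transcript length 2 and the replicate block 19, all among the 107. Pairing by replicate number was weak at most, since 18 correlations of residuals between libraries with a shared number ran from -0.16 to 0.18. The shared number was the best match in 8 of 18 cases. Between wild-type DMSO and wild-type sorafenib it was the best match each time, at 0.08, 0.08 and 0.05, so pairing was not excluded. With the length offset, 2867 genes were called for sorafenib in wild type, 4092 for sorafenib in ARID1B-KO, 2189 for ARID1B-KO in DMSO and 2046 for ARID1B-KO in sorafenib. The Pearson correlation of the responses, 0.607, was 0.215 with no filter on low counts, 0.458 with DESeq2, 0.554 with the length offset, 0.588 with the replicate block and 0.651 without switching genes, a setting that removed 181 genes. With an estimated correlation camera called 0 pairs of list and contrast, against 57. Leaving out each library in turn gave 3587 to 4762 genes for sorafenib in wild type, 5143 to 6076 in ARID1B-KO, 2529 to 3851 for ARID1B-KO in DMSO, 2479 to 3596 in sorafenib and 5 to 138 for the interaction, from 5 without wild-type sorafenib replicate 2 to 138 without ARID1B-KO sorafenib replicate 3. In the same fits the Pearson correlation ran from 0.493 to 0.537, the slope from 1.058 to 1.625 and the list pairs from 55 to 64. Every one of these correlations lay under the 0.607 of the full data. Each of these fits repeated the filter on low counts with a library fewer, so the genes tested could differ too. For all of these differences between settings the cause was not tested. Of 340 values of named genes, 339 kept their side of the threshold with DESeq2 size factors, 334 with no filter, 328 with DESeq2, 301 with the length offset and 325 with the replicate block, and none changed sign past the threshold. Of 57 list calls, 56 held with DESeq2 size factors, 52 with no filter, 57 with the replicate block and 49 without shifted windows, where 5 were lost and the 3 calls of histones had too few members left to test. In fry, which tests a list against no change rather than against other genes, 49 of the 57 passed in the same direction. At the real depth and with 3 libraries per group, the self-test recovered 40.3% of genes changed 2-fold in the interaction.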

Other observations

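The genes in these first paragraphs were chosen after their values were seen, from lists that camera did not call. However, BBC3 is also a listed p53 target, SLC7A11 a listed ATF4 gene and AXL a listed YAP and TEAD target. Camera called those lists in the same contrasts. The tests of averaged effects and of contrasts with no shared library were also chosen after the result was seen. In wild type with sorafenib the pro-apoptotic BBC3 rose (1.06 ± 0.14) and the anti-apoptotic BCL2L1 fell (-0.71 ± 0.08), while 4 of 16 BCL2 family genes rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.662). The iron hormone gene HAMP rose (2.77 ± 0.23) and the cystine transporter gene SLC7A11 fell (-1.97 ± 0.14), and of 25 ferroptosis and iron genes 8 rose and 7 fell under both adjustments (camera adjusted p = 0.776). Of 30 glycolysis and hypoxia genes 3 rose and 11 fell under both adjustments (camera adjusted p = 0.103), with the glucose transporter gene SLC2A1 at -2.55 ± 0.22 and NDRG1 at 2.31 ± 0.13. The interferon-stimulated gene IFIT1 rose by 1.61 ± 0.16 in wild type and 2.34 ± 0.16 in ARID1B-KO. Of 28 interferon-stimulated genes 10 rose and 2 fell in wild type, and 11 and 2 adjusted over the list alone (camera adjusted p = 0.0714), and 13 rose and 6 fell in ARID1B-KO, and 15 and 6 adjusted over the list alone (camera adjusted p = 0.0661). HOXD3 (-4.34 ± 0.74) and HOXD4 (-2.66 ± 0.65) fell in wild type. The 9 HOX genes had a median of 0.10, a mean of -1.08 and a test directed down, with 1 higher and 3 lower under both adjustments (camera adjusted p = 0.332).

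Between the genotypes in DMSO, SMARCA2, an ATPase of the BAF complex, was lower in ARID1B-KO (-1.31 ± 0.10), as was the subunit gene SMARCC2 (-0.71 ± 0.10), and BCL7A was higher (0.84 ± 0.11). Of 27 BAF and PBAF subunits 4 were higher and 3 lower, and 3 and 3 adjusted over the list alone (camera adjusted p = 0.887). Among 19 genes of epithelial to mesenchymal transition 7 were higher and 10 lower under both adjustments (camera adjusted p = 0.299). The transcription factor SNAI2 was higher (4.41 ± 0.58), and the actin-binding TAGLN (-3.99 ± 0.17) and the receptor kinase AXL (-2.52 ± 0.41) were lower. The progenitor markers CD24 (2.18 ± 0.14) and DLK1 (1.26 ± 0.17) were higher, with 4 of 17 fetal liver and progenitor genes higher and 3 lower under both adjustments (camera adjusted p = 0.948).

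Loss of ARID1B and sorafenib may share part of their effect on gene expression, as a hypothesis. Of genes called both for ARID1B-KO in DMSO and for sorafenib in wild type, 584 were higher in both, 411 lower in both, 292 higher in ARID1B-KO and lower with sorafenib, and 314 the reverse, where independent lists would share 319, 312, 329 and 303. Both contrasts use the wild-type DMSO libraries, which alone gives a positive covariance. The covariance was 0.0845, against a mean of 0.0521 and a highest of 0.0639 in 50 simulations of unchanged groups. With the genotype effect averaged over treatments and the sorafenib effect averaged over genotypes, in which shared noise nearly cancels, the covariance was 0.0413 (interval 0.0297 to 0.0532 over resampled genes, which are not independent; jackknife SE over libraries 0.012, and 0.0282 to 0.0539 with each library left out) and the Pearson correlation 0.095. These values argue against the shared libraries alone. With different wild-type DMSO libraries in each contrast, the covariance was above 0 in all 6 ways to divide them (0.0023 to 0.0498), but its mean of 0.0299 lay under 2 SD (SD 0.016), so this test did not decide.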
